A study of Mus musculus with 18 samples.

How the data were processed

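The aligner, the counting tool, the gene annotation and the strand of the libraries are not given in the sources used here; the submitters' processing notes name the genome build GRCm38.p6. RNA had been extracted with Trizol from spleen CD8 T cells isolated with a naive CD8 T cell kit and sequenced on a NextSeq instrument, for 18 libraries in 6 groups of 3: WT, Card11 E134G and Card11 K215M mice, each naive or stimulated for 24 h through CD3 and CD28. The deposited table holds raw read counts per gene name, whole numbers for 55284 of its 55494 names, and no value in any library for the other 210. Columns of the activated libraries carry the word Soluable, which the sample labels do not use; these columns were taken as the stimulated samples because the labels give no other condition, and EG and KM as E134G and K215M. All 18 columns were mapped to a sample. Library totals ran from 9663773 to 18880278 counts. Because the strand is not known, counts of genes that overlap another gene on the opposite strand are uncertain, as are those of close paralogs (the granzyme, Bcl2a1, Ly6c, Klra and Gbp families and immunoglobulin segments). The 37 mitochondrial names had 0 counts in every library.

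Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with the groups (15136 of the 30662 names with at least 1 count), scaled by the trimmed mean of M-values, and fitted with 1 quasi-likelihood model of the 6 group means over all libraries with robust dispersion (12 residual degrees of freedom, common biological coefficient of variation 10.5%). Two-sided quasi-likelihood F-tests were made for 11 comparisons, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Principal components used log2 CPM with a prior count of 2. Gene positions came from the RefSeq annotation of GRCm38.p6, which matched 13802 of the tested names.

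Before the data were examined, the comparisons, the tests, all alternatives except those named as added, the rule for naming genes and 31 gene lists were fixed. The lists cover T cell programs, markers of other cell types and signs of RNA quality. Lists with at least 5 tested genes were tested with limma's camera (competitive, two-sided, inter-gene correlation preset at 0.01, Benjamini-Hochberg over the lists of a comparison). Camera with an estimated correlation and fry were the alternatives. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. The naming rule took Card11, 20 readout genes, the 8 largest changes in each direction (5 for comparisons of the mutants and interactions) among called genes with a mean of at least 5 CPM and no overlap between libraries, skipping predicted genes, pseudogenes, immunoglobulin and T cell receptor segments, mitochondrial and sex-linked genes, and up to 3 called members per list with the smallest p, or other members as examples. Genes outside it are named as chosen after their values were seen. A group without a count was set at a bound of 3 counts. Fewer genes are named than the rule allows.

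Alternatives for the gene tests were DESeq2's size factors in the edgeR fit, total counts, no low-count filter, DESeq2's own test, the compared groups alone, the replicate number as a block, genotype and replicate number together as a block, and leaving out each library. Libraries with the same number were not treated as pairs: of 45 correlations between the residuals of libraries with the same number in different groups, 5 were over 0.1, and they ranged from -0.489 to 0.622 over 8938 genes. Libraries 1 and 2 alone were added as an alternative after seeing that library 3 lay between the others. The tests were run on simulated data with known changes. For a comparison of 3 against 3 libraries they recovered 67.2% of 1.5-fold, 97% of 2-fold and 100% of 4-fold changes, with 9 calls among unchanged genes (4.86% of all calls). For an interaction they recovered 29.9%, 83.6% and 97%, with 5 such calls (3.45%).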

Results

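RNA was sequenced from CD8 T cells isolated from the spleens of mice of 3 genotypes: wild type (WT), Card11 E134G and Card11 K215M. Card11 encodes the scaffold of the CARD11-BCL10-MALT1 complex, which carries antigen receptor signals to NF-kB, and both changes are known from human CARD11 as gain-of-function changes. Cells of each genotype were taken as naive cells or after 24 h of stimulation with antibodies to CD3 and CD28, with 3 libraries in each of the 6 groups. The naive libraries held 9663773 to 12867728 gene counts each and the activated libraries 13730425 to 18880278. In all, 15136 genes had enough counts to be tested. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, so every p-value below measures the spread between these libraries, which may be technical. In each group, library 3 lay between libraries 1 and 2 for 67.9% to 90.1% of the genes that differed within the group. A random order gives 33.3% on average. If library 3 is a pool of libraries 1 and 2, the residual degrees of freedom are overstated and the p-values too small. Log2 fold changes are given with their standard error (±) and levels as mean CPM (counts scaled to the size of the library) ± SD, with 3 libraries per group throughout.

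The first principal component of all 18 libraries held 55% of the variance and ordered the activated WT and K215M libraries (72.6 to 107.5) away from all naive libraries (-66.3 to -42.6). The E134G activated libraries lay at -24.2 to -20.6, nearer to the naive libraries, and stood apart from all other groups on the second component (17% of the variance), at 70.9 to 77.8. The root mean square log2 distance between group members was 0.401 to 0.537 within groups and 1.15 between E134G activated and WT activated libraries. It was 0.661 between K215M activated and WT activated libraries.

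**Figure D1:**
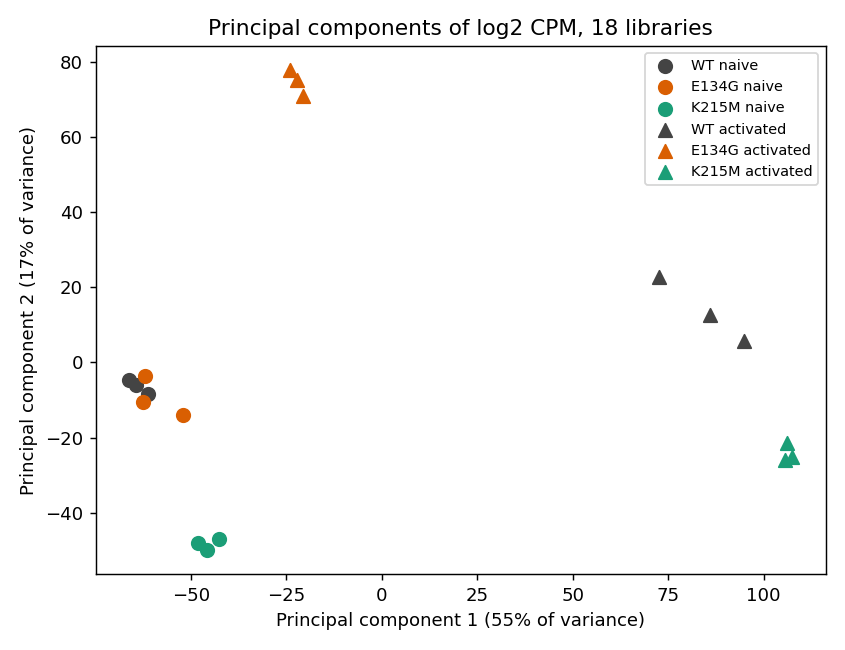
Principal components 1 (x axis, 55% of the variance) and 2 (y axis, 17%) of log2 CPM, in arbitrary component units, with 1 point per library (circles naive, triangles activated, colour for genotype). The 3 E134G activated libraries lie at -24.2 to -20.6 on component 1, between the naive libraries and the other activated libraries at 72.6 to 107.5.

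Card11 was measured first. The gene, protein coding, lies on chromosome 5 at 140872999 to 141000596 (RefSeq annotation of GRCm38.p6). Its level was 196 ± 9.31 CPM in WT naive, 143 ± 15.6 in E134G naive and 148 ± 7.7 in K215M naive libraries, and 81.2 ± 12.5, 127 ± 1.77 and 60.9 ± 8.63 CPM after activation. Card11 RNA fell on activation in WT cells (-1.27 ± 0.11) and in K215M cells (-1.28 ± 0.11), while in E134G cells the change was -0.17 ± 0.10 (adjusted p = 0.184, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for all gene tests here). Against WT, it was lower in naive cells of both mutants (-0.46 ± 0.10 and -0.41 ± 0.10, adjusted p = 0.00796 and 0.00623), higher in activated E134G cells (0.65 ± 0.10) and lower in activated K215M cells (-0.41 ± 0.11, adjusted p = 0.00775). The naive E134G call was lost without WT naive library 1 (adjusted p = 0.0543) or E134G naive library 2 (0.0614), the activated K215M call without WT activated library 2 (0.0809) or K215M activated library 3 (0.0524), and the naive K215M call with scaling by total counts (0.0507). With libraries 1 and 2 of each group alone, an alternative chosen after seeing the data, none of these 3 calls was made (adjusted p = 0.222 for naive E134G, 0.251 for activated K215M and 0.116 for naive K215M). A gene count cannot show a single amino acid change, so these values do not check the genotype labels.

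Activation of WT cells, the reference response, changed 10232 genes, 5226 higher and 5006 lower. Il2ra, the high-affinity chain of the interleukin-2 receptor, rose from 2.69 ± 0.25 to 780 ± 41.9 CPM (log2 fold change 8.17 ± 0.22). Ifng (interferon gamma) and Gzmb (granzyme B) rose by 5.05 ± 0.38 and 4.60 ± 0.25, and Tbx21, the transcription factor T-bet, by 4.21 ± 0.13. Il2 stood at 1 count over the 3 naive libraries and at 6.7 ± 0.735 CPM after activation. The interferon-stimulated gene Mx2 fell by 7.25 ± 0.19, and the naive-cell gene Igfbp4 by 4.05 ± 0.14. Asns, which encodes asparagine synthetase, rose by 7.87 ± 0.27, among the largest rises. On GRCm38.p6 Il2ra lies at 11642792 to 11693194 on chromosome 2, Ifng at 118441046 to 118445894 on chromosome 10 and Gzmb at 56258836 to 56262334 on chromosome 14. Adjusted p was at most 8.64e-09 (Ifng). Under the naming rule, the 8 largest falls included the pancreatic enzyme genes Ctrb1 and Cel (levels below). Every library of one group lay beyond every library of the other for 73.6% of all tested genes. Chance gives 10%, or more given the order of library 3. Sell, the lymph node homing receptor L-selectin, fell by 0.36 ± 0.11 (adjusted p = 0.00693), a call lost without WT naive library 2 or 3 or WT activated library 1 (adjusted p = 0.0901, 0.0543 and 0.062). It was also lost with libraries 1 and 2 alone (0.131).

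The gene groups fixed beforehand moved as follows in WT cells. Of 35 genes of DNA replication and the G1/S transition, 35 were higher, 0 lower and 0 not called (35 and 0 adjusted over the list alone), with Mcm5, a subunit of the replicative helicase, at 2.78 ± 0.10 (camera adjusted p = 9.5e-34, and 0.0653 with an estimated correlation). Of 33 mitosis genes, 31 were higher, 2 lower and 0 not called (31 and 2 adjusted over the list alone), with Cdk1 at 4.50 ± 0.24 (camera adjusted p = 3.81e-12, and 0.183 with an estimated correlation). Ribosome biogenesis counted 33 higher, 0 lower and 0 not called (33 and 0 adjusted over the list alone). For ribosome biogenesis camera gave an adjusted p of 7.52e-30, and 0.0653 with an estimated correlation. Amino acid transport, serine synthesis and ATF4 targets counted 28 higher, 3 lower and 0 not called (28 and 3 adjusted over the list alone, camera adjusted p = 5.11e-28). Glycolysis counted 15 higher, 4 lower and 2 not called (15 and 4 adjusted over the list alone). For glycolysis camera gave an adjusted p of 6.91e-07, and 0.104 with an estimated correlation. Slc7a5, an amino acid transporter, was at 3.71 ± 0.11 and Hk2, a hexokinase, at 4.95 ± 0.19. Cholesterol and fatty acid synthesis counted 29 higher, 2 lower and 3 not called (29 and 2 adjusted over the list alone). The list's camera adjusted p was 8.23e-12, and 0.089 with an estimated correlation. Oxidative phosphorylation counted 30 higher, 0 lower and 3 not called (30 and 0 adjusted over the list alone). The list's camera adjusted p was 0.000409, and 0.465 with an estimated correlation. T cell cytokines and chemokines counted 15 higher, 3 lower and 4 not called (15 and 4 adjusted over the list alone), with Lta at 3.68 ± 0.14 and Ccl3 at 5.29 ± 0.20. The list's camera adjusted p was 4.51e-06, and 0.089 with an estimated correlation. Activation markers and costimulatory receptors counted 20 higher, 6 lower and 1 not called (20 and 6 adjusted over the list alone). The list's camera adjusted p was 4.94e-05, and 0.118 with an estimated correlation.

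Of the 38 interferon-stimulated genes, 6 were higher, 28 lower and 4 not called (7 and 29 adjusted over the list alone) in activated WT cells (camera adjusted p = 7.52e-30, and 0.0653 with an estimated correlation), with Isg15 at -4.20 ± 0.12. Naive and stem-like genes counted 3 higher, 21 lower and 3 not called (3 and 21 adjusted over the list alone), with the gut-homing receptor Ccr9 at -3.30 ± 0.15 and the transcription factor Tcf7 at -0.69 ± 0.09. The list's camera adjusted p was 8.16e-09, and 0.118 with an estimated correlation. Immediate-early and AP-1 genes counted 8 higher, 17 lower and 4 not called (8 and 17 adjusted over the list alone): Fos was at -5.78 ± 0.26 and Nr4a3 at 5.15 ± 0.14. The list's camera adjusted p was 0.00537, and 0.448 with an estimated correlation. NF-kB targets and feedback genes counted 17 higher, 9 lower and 7 not called (17 and 9 adjusted over the list alone): Tnfrsf9 was at 3.83 ± 0.19 and Tnfaip3, which encodes an inhibitor of NF-kB signalling, at -2.93 ± 0.21, while Nfkbia (-0.20 ± 0.12, adjusted p = 0.139) did not pass the test, though it passed with the compared groups alone (0.0145). The list's camera adjusted p was 0.015, and 0.385 with an estimated correlation. CARD11-BCL10-MALT1 signalling components counted 5 higher, 15 lower and 10 not called (5 and 15 adjusted over the list alone). The list's camera adjusted p was 0.0319, and 0.22 with an estimated correlation. Homing receptors and integrins counted 6 higher, 19 lower and 4 not called (6 and 19 adjusted over the list alone). The list's camera adjusted p was 0.0118, and 0.0653 with an estimated correlation. For cytotoxic effector molecules (8 higher, 7 lower and 1 not called, 8 and 7 adjusted over the list alone, camera adjusted p = 1) the median was 0.00, the mean 0.44 and the camera direction downward. Effector transcription factors (11 higher, 7 lower and 9 not called, 11 and 7 adjusted over the list alone, camera adjusted p = 0.0743), apoptosis and survival genes (16 higher, 9 lower and 7 not called, 16 and 9 adjusted over the list alone, camera adjusted p = 0.128) and inhibitory receptors (10 higher, 8 lower and 6 not called, 10 and 8 adjusted over the list alone, camera adjusted p = 0.0756) did not pass the list test.

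Markers of several other cell types were at lower levels in the activated than in the naive WT libraries, beside all the groups above. B cell markers counted 0 higher, 17 lower and 3 not called (0 and 17 adjusted over the list alone), with Cr2 at -4.45 ± 0.26. For B cell markers camera gave an adjusted p of 0.00116, and 0.448 with an estimated correlation. Monocyte, macrophage and dendritic cell markers counted 1 higher, 20 lower and 4 not called (1 and 21 adjusted over the list alone), with Csf1r at -4.47 ± 0.29. The list's camera adjusted p was 7.9e-05, and 0.183 with an estimated correlation. Granulocyte markers counted 1 higher, 11 lower and 3 not called (1 and 11 adjusted over the list alone), with Mmp9 at -4.61 ± 0.42. The list's camera adjusted p was 0.0184, and 0.242 with an estimated correlation. Plasma cell markers (5 higher, 3 lower and 5 not called, 5 and 3 adjusted over the list alone, camera adjusted p = 1), NK and gamma-delta T cell markers (1 higher, 10 lower and 4 not called, 1 and 10 adjusted over the list alone, camera adjusted p = 0.0943), erythroid markers (0 higher, 5 lower and 6 not called, 0 and 5 adjusted over the list alone, camera adjusted p = 0.141) and stromal markers (0 higher, 4 lower and 3 not called, 0 and 3 adjusted over the list alone, camera adjusted p = 0.24) did not pass the list test, and the plasma cell list holds Irf4, which activated T cells also express. The CD4 and regulatory T cell list, which holds the activation genes Il2ra, Tnfrsf4 and Ctla4, counted 8 higher, 1 lower and 4 not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.0067, and 0.089 with an estimated correlation). Heat shock genes counted 5 higher, 6 lower and 2 not called (5 and 6 adjusted over the list alone, camera adjusted p = 0.824), with a median of 0.02 and a mean of -0.81. No mitochondrially encoded mRNA had a count, so that list could not be tested, and of the sex-linked list only Xist was tested (-0.38 ± 0.20, adjusted p = 0.1). Xist did not pass there, but passed without the low-count filter (adjusted p = 0.00614) and with the compared groups alone (0.000197).

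In E134G cells, activation changed 7416 genes, 3720 higher and 3696 lower. Il2ra rose from 1.75 ± 0.247 to 26.9 ± 8.26 CPM (3.94 ± 0.24), while Ifng and Gzmb fell by 3.65 ± 0.89 and 3.61 ± 0.44 and Tbx21 by 1.33 ± 0.13. Myc, a driver of growth programs, fell by 1.40 ± 0.12, and Sell rose by 0.77 ± 0.11. Mitosis genes counted 0 higher, 29 lower and 4 not called (1 and 29 adjusted over the list alone), with Top2a at -2.31 ± 0.20. For mitosis genes camera gave an adjusted p of 6.63e-11, and 0.372 with an estimated correlation. DNA replication genes counted 2 higher, 18 lower and 15 not called (2 and 18 adjusted over the list alone). For DNA replication genes camera gave an adjusted p of 0.00176, and 0.703 with an estimated correlation. Interferon-stimulated genes counted 0 higher, 34 lower and 4 not called (0 and 34 adjusted over the list alone, camera adjusted p = 1.42e-75), with Isg15 at -4.22 ± 0.13. Immediate-early genes counted 6 higher, 22 lower and 1 not called (6 and 22 adjusted over the list alone), with Jun at -5.93 ± 0.25. The list's camera adjusted p was 1.65e-12, and 0.326 with an estimated correlation. Amino acid transport and ATF4 targets counted 21 higher, 5 lower and 5 not called (22 and 5 adjusted over the list alone), with Trib3 at 3.06 ± 0.18 and Slc1a4 at 4.82 ± 0.30. The list's camera adjusted p was 2.35e-06, and 0.372 with an estimated correlation. Erythroid markers (1 higher, 8 lower and 2 not called, 1 and 8 adjusted over the list alone, camera adjusted p = 0.00146, and 0.372 with an estimated correlation) and granulocyte markers (2 higher, 9 lower and 4 not called, 2 and 9 adjusted over the list alone, camera adjusted p = 0.0117, and 0.372 with an estimated correlation) were lower in the same activated libraries. Of 25 monocyte, macrophage and dendritic cell markers, 0 were higher, 14 lower and 11 not called (0 and 14 adjusted over the list alone) (camera adjusted p = 0.000872, and 0.372 with an estimated correlation). Of 13 heat shock genes, 0 were higher, 12 lower and 1 not called (0 and 13 adjusted over the list alone) (camera adjusted p = 5.71e-11, and 0.326 with an estimated correlation). The largest adjusted p among the genes named was 0.00325 (Ifng). With libraries 1 and 2 of each group alone, an alternative chosen after seeing the data, 4122 genes were called.

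In K215M cells, activation changed 10901 genes, 5349 higher and 5552 lower. Il2ra rose from 11.8 ± 0.615 to 801 ± 137 CPM (6.08 ± 0.18), Ifng by 2.90 ± 0.29 and Gzmb by 2.94 ± 0.22. Bcat1, a branched-chain aminotransferase, rose by 6.40 ± 0.16, among the largest rises the naming rule picked. DNA replication genes counted 34 higher, 0 lower and 1 not called (34 and 0 adjusted over the list alone, camera adjusted p = 9.47e-31), with Mcm5 at 2.86 ± 0.10. Mitosis genes counted 29 higher, 1 lower and 3 not called (29 and 1 adjusted over the list alone). For mitosis genes camera gave an adjusted p of 1.22e-06, and 0.296 with an estimated correlation. Amino acid transport and ATF4 targets counted 28 higher, 0 lower and 3 not called (28 and 0 adjusted over the list alone, camera adjusted p = 4e-30), with Trib3 at 6.18 ± 0.20. Homing receptors and integrins counted 4 higher, 22 lower and 3 not called (4 and 22 adjusted over the list alone, camera adjusted p = 2.83e-05), with Cxcr4 at -4.45 ± 0.21 and Ccr9 at -3.18 ± 0.15. All 15 tested granulocyte markers were lower (camera adjusted p = 9.47e-09), with S100a9 at -5.33 ± 0.26, and so were all 20 B cell markers (camera adjusted p = 7.89e-07, and 0.296 with an estimated correlation), with Ighm at -2.44 ± 0.11. Of 25 monocyte, macrophage and dendritic cell markers, 1 were higher, 23 lower and 1 not called (1 and 23 adjusted over the list alone) (camera adjusted p = 2.16e-05, and 0.2 with an estimated correlation). The largest adjusted p among these genes was 1.94e-07 (Ifng).

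**Figure D2:**
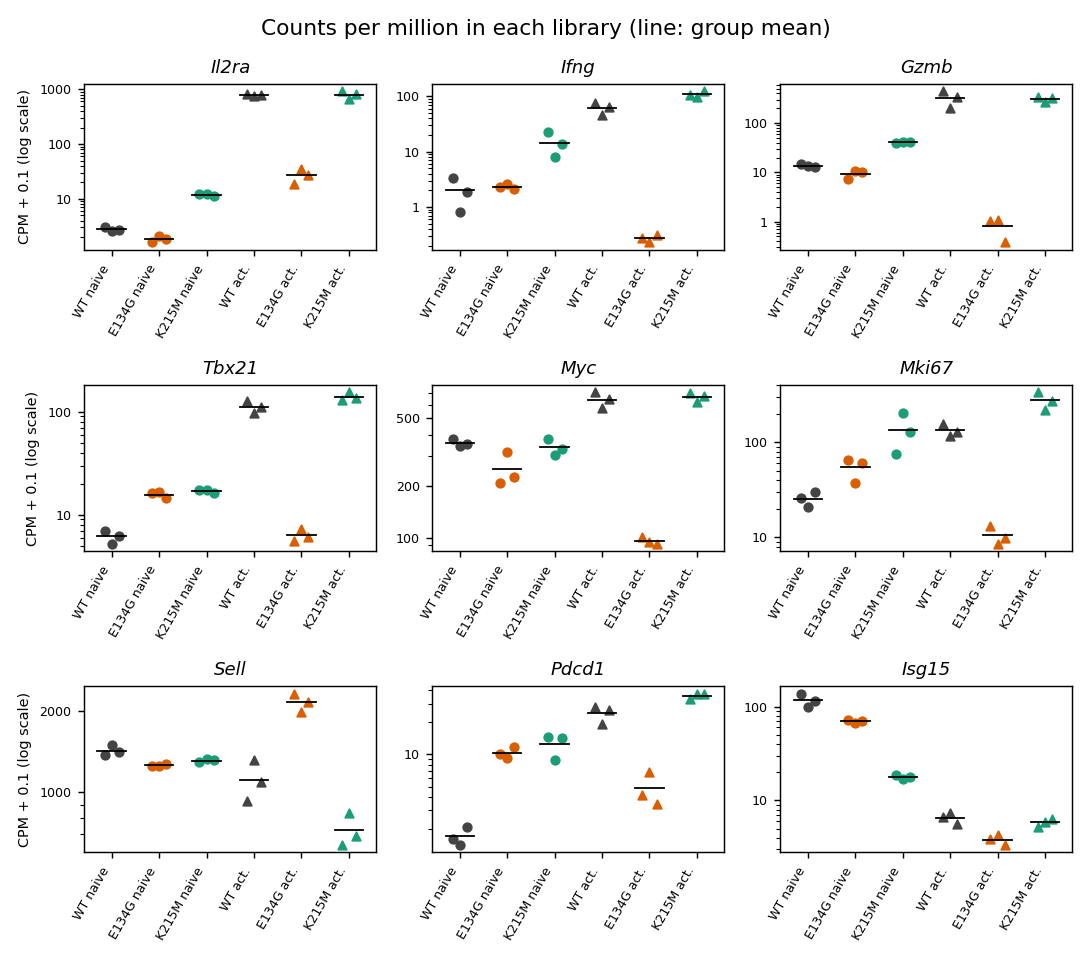
CPM of 9 genes in each of the 18 libraries (y axis, CPM + 0.1 on a log scale; x axis, group), with 1 point per library and a line at the group mean. After activation Il2ra averaged 780 CPM in WT, 26.9 in E134G and 801 in K215M libraries, and Isg15 was lower in naive K215M than in naive WT libraries.

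Activated E134G cells were next compared with activated WT cells, and 9968 genes differed, 5150 higher and 4818 lower in E134G. Ifng stood at 0.172 ± 0.0401 CPM in E134G against 62.8 ± 14.8 in WT (-8.45 ± 0.52), and Gzmb at 0.73 ± 0.391 against 328 ± 121 (-8.76 ± 0.35). Il2ra (-4.86 ± 0.17), Tbx21 (-4.17 ± 0.12), Irf4, a transcription factor induced by T cell receptor signals (-3.36 ± 0.15), Myc (-2.75 ± 0.13) and Tnf (-2.71 ± 0.17) were lower. Sell (0.96 ± 0.11) and Tcf7 (1.22 ± 0.09) were higher. Lif, a cytokine, and Mcm10, a replication factor, had some of the largest falls under the naming rule (-7.67 ± 0.29 and -6.93 ± 0.27), and F2rl1, a protease-activated receptor, one of the largest rises (3.83 ± 0.10). Adjusted p was at most 1.82e-07 (Sell). Libraries of both groups did not overlap for 73.3% of all tested genes, against 10% by chance, or more given the order of library 3.

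The growth and division groups were lower in activated E134G cells. All 35 DNA replication genes were lower (35 adjusted over the list alone, camera adjusted p = 8.89e-40), with Mcm5 at -3.13 ± 0.10. Of 33 mitosis genes, 1 were higher, 31 lower and 1 not called (1 and 31 adjusted over the list alone), with Aurkb at -4.80 ± 0.21 and Cdk1 at -5.18 ± 0.25 (camera adjusted p = 5.14e-17, and 0.14 with an estimated correlation). All 33 ribosome biogenesis genes were lower (33 adjusted over the list alone, camera adjusted p = 1.05e-43), with Nolc1 at -2.50 ± 0.09. Amino acid transport and ATF4 targets counted 1 higher, 28 lower and 2 not called (1 and 30 adjusted over the list alone, camera adjusted p = 6.15e-20), with Psat1, an enzyme of serine synthesis, at -3.35 ± 0.12. Oxidative phosphorylation counted 0 higher, 32 lower and 1 not called (0 and 32 adjusted over the list alone), with Cycs (cytochrome c) at -2.35 ± 0.11. The list's camera adjusted p was 9.47e-07, and 0.395 with an estimated correlation. Glycolysis counted 3 higher, 15 lower and 3 not called (3 and 15 adjusted over the list alone), with Hk2 at -4.90 ± 0.18. For glycolysis camera gave an adjusted p of 9.55e-08, and 0.106 with an estimated correlation. Cholesterol and fatty acid synthesis counted 1 higher, 27 lower and 6 not called (1 and 28 adjusted over the list alone), with Idi1 at -2.77 ± 0.15. The list's camera adjusted p was 2.14e-07, and 0.167 with an estimated correlation. Heat shock genes counted 0 higher, 10 lower and 3 not called (0 and 10 adjusted over the list alone), with Hspd1 at -3.32 ± 0.13. For heat shock genes camera gave an adjusted p of 9.81e-07, and 0.187 with an estimated correlation.

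Effector and signalling groups also differed. T cell cytokines and chemokines counted 3 higher, 15 lower and 4 not called (4 and 15 adjusted over the list alone, camera adjusted p = 5.88e-08), with Lta at -3.84 ± 0.13 and Ccl3 at -4.89 ± 0.19. The median of this list was -3.15, and -2.85 with Il10, which had no count in activated E134G cells, set at its bound of 3 counts. Activation markers counted 4 higher, 20 lower and 3 not called (4 and 20 adjusted over the list alone), with the transferrin receptor Tfrc at -2.82 ± 0.10 and Il12rb1 at -4.65 ± 0.16. For activation markers camera gave an adjusted p of 3.03e-05, and 0.14 with an estimated correlation. NF-kB targets and feedback genes counted 4 higher, 21 lower and 8 not called (4 and 22 adjusted over the list alone), with Bcl2l1, a survival gene, at -3.89 ± 0.09. The list's camera adjusted p was 7.71e-05, and 0.187 with an estimated correlation. Nfkbia (-0.08 ± 0.12, adjusted p = 0.563) did not pass the test, and its sign changed with scaling by total counts (0.0083). Tnfaip3 (-0.44 ± 0.19, adjusted p = 0.0531) did not pass either, but passed without the low-count filter (adjusted p = 9.97e-08), with the replicate number as a block (0.0487), with the compared groups alone (7.11e-05) and with DESeq2 (0.0366). CARD11-BCL10-MALT1 signalling components counted 18 higher, 5 lower and 7 not called (19 and 6 adjusted over the list alone), with Ikbkb, a kinase of the NF-kB pathway, at 0.71 ± 0.08 and Prkcq at 0.68 ± 0.09. The list's camera adjusted p was 0.0455, and 0.245 with an estimated correlation. That list call was lost with the replicate number as a block (adjusted p = 0.0527). Naive and stem-like genes counted 22 higher, 2 lower and 3 not called (22 and 2 adjusted over the list alone), with Dapl1 at 2.20 ± 0.13. The list's camera adjusted p was 1.12e-07, and 0.167 with an estimated correlation. Homing receptors and integrins counted 19 higher, 7 lower and 3 not called (19 and 7 adjusted over the list alone, camera adjusted p = 0.00805), with Itgae at 3.07 ± 0.21 and Ccr9 at 1.97 ± 0.15. Interferon-stimulated genes counted 10 higher, 23 lower and 5 not called (10 and 23 adjusted over the list alone), with Gbp2 at -3.39 ± 0.13. The list's camera adjusted p was 0.00136, and 0.474 with an estimated correlation. Genes of the memory-like list went both ways (16 higher, 11 lower and 3 not called, 16 and 11 adjusted over the list alone, camera adjusted p = 0.909): the median was 0.74, the mean 0.33 and the camera direction downward, and Cd44 was at -2.61 ± 0.12. Cytotoxic molecules (6 higher, 6 lower and 4 not called, 6 and 6 adjusted over the list alone, camera adjusted p = 0.217) had a median of 0.01 and a mean of -0.95. Prf1 (perforin) was higher by 0.28 ± 0.12 (adjusted p = 0.0485), a call lost without WT activated library 1, 2 or 3 or E134G activated library 2 or 3 (adjusted p = 0.0596, 0.197, 0.0512, 0.165 and 0.156). It was also lost without the low-count filter (0.14), with the replicate number as a block (0.0514), with the compared groups alone (0.0667), with DESeq2 (0.0727) and with libraries 1 and 2 of each group alone (0.222).

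Markers of other cell types also differed in the activated E134G libraries, beside the groups above. B cell markers counted 18 higher, 0 lower and 2 not called (18 and 0 adjusted over the list alone), with Cr2 at 2.21 ± 0.29. For B cell markers camera gave an adjusted p of 0.00436, and 0.494 with an estimated correlation. Granulocyte markers counted 13 higher, 0 lower and 2 not called (13 and 0 adjusted over the list alone), with S100a9 at 1.82 ± 0.22. For granulocyte markers camera gave an adjusted p of 0.00618, and 0.187 with an estimated correlation. Monocyte, macrophage and dendritic cell markers counted 16 higher, 1 lower and 8 not called (16 and 1 adjusted over the list alone). The list's camera adjusted p was 0.0411, and 0.43 with an estimated correlation. The CD4 and regulatory T cell list, which holds Il2ra and Tnfrsf4, counted 2 higher, 9 lower and 2 not called (2 and 9 adjusted over the list alone, camera adjusted p = 0.0251, and 0.14 with an estimated correlation). Cd8a, a chain of CD8 chosen after its values were seen, stood at 818 ± 97.7 CPM in E134G and 954 ± 34.1 in WT activated libraries. Of the genes at least 4-fold higher on activation in both WT and K215M cells, 550 in all, 146 rose, 133 fell and 271 were not called in E134G cells (median log2 fold change 0.03). Of the 889 genes at least 4-fold lower in both, 612 fell, 9 rose and 268 were not called (median -1.80).

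In activated K215M cells, 3707 genes differed from activated WT cells, 2115 higher and 1592 lower. Havcr2, which encodes the inhibitory receptor TIM-3, was higher by 2.92 ± 0.25, Entpd1 (CD39) by 1.97 ± 0.25, and the transcription factor Maf by 2.44 ± 0.26. The costimulatory receptors Tnfrsf4 (1.04 ± 0.12) and Tnfrsf9 (0.79 ± 0.15) and the chemokine Ccl5 (2.58 ± 0.25) were higher, and Il7r (-1.86 ± 0.15), Sell (-0.61 ± 0.11), Prf1 (-0.81 ± 0.13) and Eomes (-0.56 ± 0.12) were lower. Plagl1, a zinc finger gene, had one of the largest rises (3.61 ± 0.22), and so had Arsb (2.74 ± 0.13), whose level in the WT activated libraries was below that in every library of the other 5 groups. Adjusted p was at most 0.00232 (Eomes). Calls of Tnfrsf9, Sell and Eomes were lost with libraries 1 and 2 of each group alone (adjusted p = 0.0894, 0.111 and 0.139), as were those of Ifng and Pdcd1 described below (0.402 and 0.264). Il2ra (0.04 ± 0.14, adjusted p = 0.877) and Gzmb (-0.08 ± 0.20, adjusted p = 0.805) did not pass the test: Il2ra turned negative without K215M activated library 1 (-0.068) and Gzmb positive without WT activated library 1 (0.21) or K215M activated library 2 (0.025). Ifng was higher (0.80 ± 0.26, adjusted p = 0.0334), a call lost without WT activated library 2 or 3 or K215M activated library 1 or 3 (adjusted p = 0.157, 0.0777, 0.0633 and 0.122) and with DESeq2 (0.167). Pdcd1, which encodes the inhibitory receptor PD-1, was higher by 0.54 ± 0.18 (adjusted p = 0.0391), a call lost without WT activated library 2 or 3 or K215M activated library 2 or 3 (adjusted p = 0.196, 0.0654, 0.0931 and 0.113), with total counts (0.0552) and with DESeq2 (0.0667). Tnf (0.04 ± 0.15, adjusted p = 0.88) did not pass, and turned negative without WT activated library 2 (-0.015) or K215M activated library 1 (-0.0025).

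Genes of cell division were higher together in activated K215M cells. Of 33 mitosis genes, 32 were higher, 0 lower and 1 not called (32 and 0 adjusted over the list alone), with Ube2c at 1.47 ± 0.19 and Plk1 at 1.15 ± 0.18 (camera adjusted p = 5.72e-16, and 0.21 with an estimated correlation). Of 35 DNA replication genes, 33 were higher, 0 lower and 2 not called (35 and 0 adjusted over the list alone), with Tk1 at 0.92 ± 0.11 and Tyms at 0.91 ± 0.12 (camera adjusted p = 5.69e-16, and 0.21 with an estimated correlation). The proliferation marker Mki67 was higher by 1.04 ± 0.30 (adjusted p = 0.0234), a call lost without WT activated library 2 or 3 or K215M activated library 1 or 3 (adjusted p = 0.104, 0.0686, 0.0728 and 0.0584). It was also lost with libraries 1 and 2 alone (0.275). Glycolysis counted 13 higher, 1 lower and 7 not called (14 and 2 adjusted over the list alone), with the lactate transporter Slc16a3 at 1.87 ± 0.24. For glycolysis camera gave an adjusted p of 3.63e-05, and 0.21 with an estimated correlation. Oxidative phosphorylation counted 17 higher, 0 lower and 16 not called (28 and 0 adjusted over the list alone). The list's camera adjusted p was 8.18e-06, and 0.471 with an estimated correlation. Amino acid transport and ATF4 targets counted 13 higher, 0 lower and 18 not called (14 and 0 adjusted over the list alone), with Asns at 1.22 ± 0.14. The list's camera adjusted p was 1.06e-05, and 0.221 with an estimated correlation. Inhibitory receptors counted 11 higher, 4 lower and 9 not called (15 and 4 adjusted over the list alone). For inhibitory receptors camera gave an adjusted p of 0.011, and 0.221 with an estimated correlation. Memory-like genes counted 10 higher, 5 lower and 15 not called (12 and 5 adjusted over the list alone), with the killer lectin receptor Klrc1 at 2.02 ± 0.24. For memory-like genes camera gave an adjusted p of 0.0474, and 0.401 with an estimated correlation. That list call was lost with the replicate number as a block (adjusted p = 0.0583). Interferon-stimulated genes counted 0 higher, 22 lower and 16 not called (0 and 24 adjusted over the list alone), with Xaf1 at -1.93 ± 0.15 and Oas2 at -1.85 ± 0.17. The list's camera adjusted p was 2.55e-18, and 0.21 with an estimated correlation. Naive and stem-like genes counted 2 higher, 13 lower and 12 not called (2 and 15 adjusted over the list alone), with Igfbp4 at 1.76 ± 0.14 and Dapl1 at 1.38 ± 0.13 going the other way. The list's camera adjusted p was 1.06e-05, and 0.277 with an estimated correlation. CARD11-BCL10-MALT1 signalling components counted 0 higher, 8 lower and 22 not called (1 and 8 adjusted over the list alone), with Ikbkb at -0.42 ± 0.08, a call lost with libraries 1 and 2 of each group alone (adjusted p = 0.113). The list's camera adjusted p was 0.011, and 0.21 with an estimated correlation. NF-kB targets (3 higher, 3 lower and 27 not called, 3 and 2 adjusted over the list alone, camera adjusted p = 0.685) did not pass the list test.

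Plasma cell markers (5 higher, 0 lower and 8 not called, 6 and 0 adjusted over the list alone, camera adjusted p = 4.51e-05, and 0.21 with an estimated correlation) and erythroid markers (7 higher, 0 lower and 4 not called, 7 and 0 adjusted over the list alone, camera adjusted p = 3.05e-05, and 0.21 with an estimated correlation) were higher in the same K215M libraries, with Jchain, of secreted antibody, at 3.51 ± 0.27 and the globin gene Hbb-bs at 3.08 ± 0.41. The CD4 and regulatory T cell list, which shares Tnfrsf4 with the activation list, counted 6 higher, 1 lower and 6 not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.00159, and 0.21 with an estimated correlation). The number of genes called in activated K215M cells was 1905 without WT activated library 2, 2325 without K215M activated library 3 and 500 with libraries 1 and 2 of each group alone, the last chosen after seeing the data. The share of calls that were higher was 57.1%, against 46.8% with total counts, 37.6% without the low-count filter, 45.7% with the compared groups alone and 45.4% with libraries 1 and 2 alone.

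In naive E134G cells, 1252 genes differed from naive WT cells, 665 higher and 587 lower. Pdcd1 was higher by 2.68 ± 0.29, Tbx21 by 1.37 ± 0.14, Ccl5 by 2.28 ± 0.24 and Ikzf2 (Helios) by 1.97 ± 0.19. Spry2, a regulator of receptor signalling (3.06 ± 0.22), Nrgn (3.40 ± 0.31) and the Ly49 family gene Klra6 (3.10 ± 0.39) were among the largest rises, though reads of Klra6 can be shared with its close paralogs. Adjusted p was at most 2.53e-05 (Klra6). Lars2 (below) and Erdr1 (4.97, chosen after its value was seen) rose more than these genes. Gzmk (granzyme K) stood at 1.37 ± 0.73 CPM in E134G naive cells and at 1 count over the 3 WT naive libraries. Memory-like CD8 T cell genes counted 16 higher, 2 lower and 12 not called (17 and 3 adjusted over the list alone, camera adjusted p = 4.98e-10), with Anxa2 at 1.61 ± 0.17. Interferon-stimulated genes counted 0 higher, 30 lower and 8 not called (0 and 34 adjusted over the list alone, camera adjusted p = 6.94e-56), with Gbp5 at -1.36 ± 0.10, Isg20 at -1.17 ± 0.10 and Ifit2 at -1.28 ± 0.11. Mitosis genes counted 19 higher, 0 lower and 14 not called (27 and 0 adjusted over the list alone), with Nusap1 at 1.55 ± 0.25 and Top2a at 1.10 ± 0.19. For mitosis genes camera gave an adjusted p of 3.59e-19, and 0.129 with an estimated correlation. Inhibitory receptors counted 6 higher, 2 lower and 16 not called (8 and 3 adjusted over the list alone), with Cd160 at 1.20 ± 0.16. For inhibitory receptors camera gave an adjusted p of 0.00767, and 0.237 with an estimated correlation. NF-kB targets counted 6 higher, 2 lower and 25 not called (9 and 3 adjusted over the list alone, camera adjusted p = 0.164). Nfkbia was higher by 0.47 ± 0.12 (adjusted p = 0.0151), a call lost without WT naive library 2 or 3 or E134G naive library 2 (adjusted p = 0.0713, 0.0524 and 0.102) and with the compared groups alone (0.0768). Myc was lower (-0.51 ± 0.12, adjusted p = 0.0102), a call lost without E134G naive library 3 (0.0518). Top2a, Nfkbia and Myc lost their calls with libraries 1 and 2 alone (adjusted p = 0.115, 0.267 and 0.388).

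Other markers differed beside these groups. Granulocyte markers counted 8 higher, 0 lower and 7 not called (8 and 0 adjusted over the list alone, camera adjusted p = 9.8e-10), with Ngp at 2.48 ± 0.28. Erythroid markers counted 7 higher, 0 lower and 4 not called (7 and 0 adjusted over the list alone), with the globin gene Hba-a1 at 2.75 ± 0.28, while the plasma cell gene Jchain was lower (-2.90 ± 0.32). For erythroid markers camera gave an adjusted p of 2.62e-10, and 0.0643 with an estimated correlation. Heat shock genes counted 0 higher, 2 lower and 11 not called (0 and 2 adjusted over the list alone), with Hspa1a at -3.23 ± 0.48, a call lost with the compared groups alone (adjusted p = 0.0573) and with libraries 1 and 2 of each group alone (0.0924). For heat shock genes camera gave an adjusted p of 0.0164, and 0.799 with an estimated correlation. Stromal and endothelial markers counted 2 higher, 0 lower and 5 not called (4 and 1 adjusted over the list alone). The list's camera adjusted p was 0.0185, and 0.0916 with an estimated correlation. Lars2, which encodes a mitochondrial leucyl-tRNA synthetase, ranged from 1250 to 2970 CPM over the E134G naive libraries and from 46.2 to 57.9 over the WT naive libraries (5.43 ± 0.88, adjusted p = 0.0021). That call was lost with libraries 1 and 2 alone (adjusted p = 0.129). The number of genes called in naive E134G cells was 731, 775 and 706 without WT naive library 1, 2 or 3, 745 and 824 without E134G naive library 2 or 3, and 115 with libraries 1 and 2 of each group alone. The share higher was 53.1%, and 63.2% with total counts. The libraries of both groups did not overlap for 30% of all tested genes. Exchangeable libraries without a difference would give 10%, but library 3 lay mostly between libraries 1 and 2, which raises that value. The 30% therefore need not exceed chance.

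In naive K215M cells, 3365 genes differed from naive WT cells, 2004 higher and 1361 lower. Ccl5 was higher by 4.51 ± 0.25, the chemokine receptor Cxcr3 by 2.46 ± 0.18, Cd44 by 1.36 ± 0.13 and the integrin Itgb1 by 1.28 ± 0.08. Gzmk stood at 17.7 ± 4.28 CPM against 1 count over the 3 WT naive libraries. Ifng (2.94 ± 0.43), Gzmb (1.58 ± 0.25), Il2ra (2.13 ± 0.24) and Tbx21 (1.49 ± 0.14) were higher before any stimulation in culture, as were Pdcd1 (2.96 ± 0.28), Havcr2 (3.02 ± 0.29) and Tox2, a factor associated with exhaustion (5.25 ± 0.45). The anti-inflammatory cytokine gene Il10 was higher by 5.48 ± 0.43. Markers of other cells were higher in these libraries too (below), so part of these and the following rises may come from such cells. Il7r, the interleukin-7 receptor of resting cells, was lower (-1.04 ± 0.15). Adjusted p was at most 0.000203 (Gzmb). There was no overlap between the libraries for 39.3% of all tested genes, against 10% by chance, which the order of library 3 raises by an unknown amount.

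Interferon-stimulated genes were lower in naive K215M cells in nearly every case: 0 higher, 36 lower and 2 not called (0 and 36 adjusted over the list alone, camera adjusted p = 8.76e-135), with Isg15 at 17.7 ± 0.845 CPM against 118 ± 18.9 in WT (-2.73 ± 0.11), Mx2 at -3.24 ± 0.14 and Oas2 at -2.91 ± 0.13. Memory-like genes counted 18 higher, 1 lower and 11 not called (21 and 2 adjusted over the list alone, camera adjusted p = 1.4e-15). Inhibitory receptors counted 16 higher, 2 lower and 6 not called (16 and 2 adjusted over the list alone, camera adjusted p = 1.71e-10). Mitosis genes counted 31 higher, 0 lower and 2 not called (31 and 0 adjusted over the list alone, camera adjusted p = 9.74e-32), with Bub1b at 2.34 ± 0.22 and Cdca8 at 1.77 ± 0.17. DNA replication genes counted 21 higher, 0 lower and 14 not called (23 and 1 adjusted over the list alone), with Tk1 at 1.58 ± 0.13. For DNA replication genes camera gave an adjusted p of 9.18e-12, and 0.183 with an estimated correlation. Effector transcription factors counted 12 higher, 4 lower and 11 not called (12 and 5 adjusted over the list alone, camera adjusted p = 0.00225), with Prdm1 (Blimp-1) at 1.84 ± 0.21. T cell cytokines counted 11 higher, 2 lower and 9 not called (12 and 2 adjusted over the list alone), with the interferon-induced Cxcl10 at -2.18 ± 0.18. For T cell cytokines camera gave an adjusted p of 1.91e-05, and 0.0781 with an estimated correlation. Homing receptors counted 12 higher, 2 lower and 15 not called (12 and 3 adjusted over the list alone, camera adjusted p = 3.13e-06). Naive and stem-like genes counted 2 higher, 9 lower and 16 not called (2 and 11 adjusted over the list alone), with Als2cl at -0.67 ± 0.08. The list's camera adjusted p was 0.00641, and 0.451 with an estimated correlation. NF-kB targets counted 8 higher, 1 lower and 24 not called (11 and 1 adjusted over the list alone, camera adjusted p = 0.0714), with Ier3 at 1.96 ± 0.23. CARD11-BCL10-MALT1 signalling components counted 3 higher, 6 lower and 21 not called (3 and 6 adjusted over the list alone, camera adjusted p = 0.0893).

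Markers of several other cell types differed in the same naive K215M libraries. Plasma cell markers counted 11 higher, 0 lower and 2 not called (12 and 0 adjusted over the list alone, camera adjusted p = 2.82e-18), with Jchain at 4.80 ± 0.21 and Iglc1 at 5.82 ± 0.30. B cell markers counted 17 higher, 0 lower and 3 not called (18 and 0 adjusted over the list alone), with Ighm at 2.56 ± 0.11; reads of immunoglobulin segments can be shared between near-identical copies. For B cell markers camera gave an adjusted p of 1.26e-11, and 0.173 with an estimated correlation. Granulocyte markers counted 10 higher, 0 lower and 5 not called (10 and 0 adjusted over the list alone, camera adjusted p = 2.06e-16), with Mpo at 6.65 ± 0.46. Erythroid markers counted 9 higher, 0 lower and 2 not called (9 and 0 adjusted over the list alone), with Slc4a1 at 6.26 ± 0.68. For erythroid markers camera gave an adjusted p of 2.79e-06, and 0.123 with an estimated correlation. CD4 and regulatory T cell markers counted 10 higher, 1 lower and 2 not called (10 and 1 adjusted over the list alone, camera adjusted p = 1.09e-08), with Cxcr5 at 1.88 ± 0.18 and Ikzf2 at 1.60 ± 0.19, and Cd4 itself stood at 16 ± 2.49 CPM against 1270 ± 17.5 for Cd8a. NK, NKT and gamma-delta T cell markers counted 6 higher, 0 lower and 9 not called (8 and 1 adjusted over the list alone). The list's camera adjusted p was 0.0144, and 0.192 with an estimated correlation. Of 25 monocyte, macrophage and dendritic cell markers, 10 were higher, 2 lower and 13 not called (11 and 3 adjusted over the list alone) (camera adjusted p = 0.0141, and 0.402 with an estimated correlation). Of 13 heat shock genes, 0 were higher, 5 lower and 8 not called (0 and 9 adjusted over the list alone) (camera adjusted p = 0.00677, and 0.451 with an estimated correlation). The share of calls that were higher was 59.6%, against 77.9% with total counts and 73.9% with libraries 1 and 2 of each group alone, a setting that called 1232 genes.

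**Figure D3:**
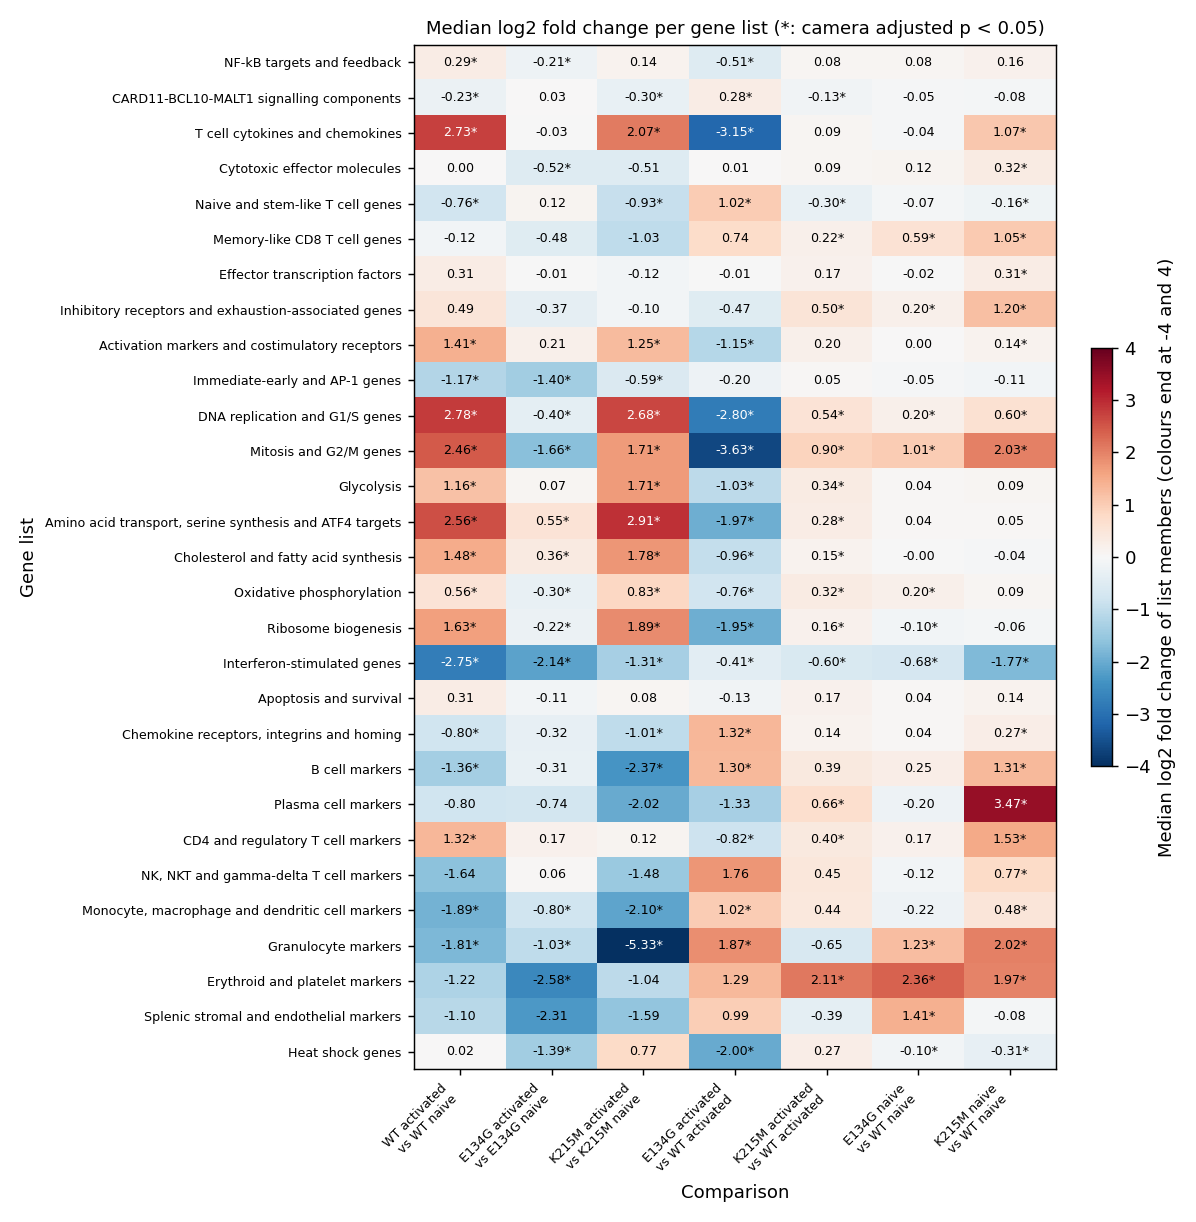
Median log2 fold change of the tested members of each of the fixed gene lists with at least 5 tested genes (y axis) in 7 comparisons (x axis), coloured from -4 to 4 and printed in each cell. A star marks a camera adjusted p under 0.05 with the preset correlation; interferon-stimulated genes had a negative median in all 7 comparisons.

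Both mutants were also compared directly. Between activated K215M and E134G cells 10831 genes differed, 5470 higher and 5361 lower in K215M. Ifng (9.24 ± 0.51), Gzmb (8.68 ± 0.35), Il2ra (4.90 ± 0.17) and Cdk1 (5.98 ± 0.25) were higher in K215M, and Sell (-1.57 ± 0.11) and Tcf7 (-1.33 ± 0.09) lower. Ribosome biogenesis counted 33 higher, 0 lower and 0 not called (33 and 0 adjusted over the list alone). For ribosome biogenesis camera gave an adjusted p of 7.4e-35, and 0.0501 with an estimated correlation. DNA replication counted 35 higher, 0 lower and 0 not called (35 and 0 adjusted over the list alone). For DNA replication camera gave an adjusted p of 1.23e-37, and 0.0501 with an estimated correlation. Granulocyte markers were lower in the K215M libraries (0 higher, 13 lower and 2 not called, 0 and 13 adjusted over the list alone, camera adjusted p = 0.00764, and 0.19 with an estimated correlation) and plasma cell markers higher (9 higher, 0 lower and 4 not called, 9 and 0 adjusted over the list alone, camera adjusted p = 0.0218, and 0.294 with an estimated correlation). Of 13 CD4 and regulatory T cell markers, 9 were higher, 0 lower and 4 not called (9 and 0 adjusted over the list alone) (camera adjusted p = 0.00564, and 0.0726 with an estimated correlation). Of 13 heat shock genes, 11 were higher, 0 lower and 2 not called (11 and 0 adjusted over the list alone) (camera adjusted p = 8.37e-06, and 0.228 with an estimated correlation). In naive cells 2998 genes differed between the mutants, 1753 higher and 1245 lower in K215M. Il10 (5.67 ± 0.45), Plagl1 (5.63 ± 0.44), Il2ra (2.75 ± 0.27) and Gzmb (2.13 ± 0.26) were higher in K215M, and Spry2 (-2.83 ± 0.21), Klra6 (-4.07 ± 0.43) and Isg15 (-1.97 ± 0.11) lower. Interferon-stimulated genes counted 3 higher, 26 lower and 9 not called (4 and 28 adjusted over the list alone, camera adjusted p = 1.27e-55). Inhibitory receptors counted 12 higher, 2 lower and 10 not called (13 and 4 adjusted over the list alone, camera adjusted p = 2.16e-06). Plasma cell markers counted 12 higher, 0 lower and 1 not called (13 and 0 adjusted over the list alone, camera adjusted p = 1.35e-25), with Jchain at 7.69 ± 0.27. B cell markers counted 12 higher, 0 lower and 8 not called (17 and 0 adjusted over the list alone). For B cell markers camera gave an adjusted p of 4.44e-10, and 0.236 with an estimated correlation. Granulocyte markers counted 6 higher, 0 lower and 9 not called (9 and 0 adjusted over the list alone, camera adjusted p = 2.16e-06). The CD4 and regulatory T cell list, which holds Il2ra, counted 10 higher, 1 lower and 2 not called (10 and 1 adjusted over the list alone, camera adjusted p = 2.01e-07). Of 15 NK and gamma-delta T cell markers, 5 were higher, 0 lower and 10 not called (5 and 1 adjusted over the list alone) (camera adjusted p = 0.0366, and 0.263 with an estimated correlation). Of 25 monocyte, macrophage and dendritic cell markers, 7 were higher, 0 lower and 18 not called (7 and 0 adjusted over the list alone) (camera adjusted p = 0.0129, and 0.42 with an estimated correlation). Pdcd1 (0.29 ± 0.22, adjusted p = 0.393) and Tbx21 (0.12 ± 0.12, adjusted p = 0.554) did not differ beyond the spread between libraries. The naive comparison called 1632 genes with the compared groups alone and 822 with libraries 1 and 2 of each group, and the share higher was 58.5%, against 73% with total counts and 75.9% with libraries 1 and 2.

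The interaction test asked which responses to activation differed between a mutant and WT. In E134G, 8401 genes responded differently, 4150 with a more positive and 4251 with a more negative change than in WT. The change was more negative for Ifng (-8.70 ± 0.94), Gzmb (-8.20 ± 0.48), Tbx21 (-5.54 ± 0.18), Pdcd1 (-5.05 ± 0.36), Myc (-2.23 ± 0.17), Mcm5 (-3.32 ± 0.14) and the ribosome biogenesis gene Nop58 (-2.36 ± 0.12), and more positive for Tcf7 (1.03 ± 0.12), Sell (1.14 ± 0.16) and Card11 (1.10 ± 0.15). The largest adjusted p among them was 3.37e-06 (Sell). Mitosis genes counted 1 higher, 31 lower and 1 not called (1 and 31 adjusted over the list alone). For mitosis genes camera gave an adjusted p of 1.32e-27, and 0.107 with an estimated correlation. Ribosome biogenesis genes counted 0 higher, 33 lower and 0 not called (0 and 33 adjusted over the list alone). For ribosome biogenesis genes camera gave an adjusted p of 4.58e-39, and 0.0621 with an estimated correlation. Naive and stem-like genes counted 22 higher, 3 lower and 2 not called (22 and 3 adjusted over the list alone). The list's camera adjusted p was 3.4e-08, and 0.18 with an estimated correlation. Of 20 B cell markers, 12 were higher, 0 lower and 8 not called (13 and 0 adjusted over the list alone) (camera adjusted p = 0.0233, and 0.59 with an estimated correlation). Of 25 monocyte, macrophage and dendritic cell markers, 9 were higher, 1 lower and 15 not called (8 and 1 adjusted over the list alone) (camera adjusted p = 0.0439, and 0.451 with an estimated correlation). Of 13 CD4 and regulatory T cell markers, 1 were higher, 8 lower and 4 not called (1 and 9 adjusted over the list alone) (camera adjusted p = 0.0418, and 0.18 with an estimated correlation). Of 13 heat shock genes, 0 were higher, 8 lower and 5 not called (0 and 8 adjusted over the list alone) (camera adjusted p = 1.36e-05, and 0.224 with an estimated correlation). With libraries 1 and 2 alone, 5480 genes were called.

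In K215M, 1542 genes responded differently from WT, 624 more positively and 918 more negatively. The change was more negative for Il2ra (-2.09 ± 0.28), Pdcd1 (-2.43 ± 0.34), Tbx21 (-1.16 ± 0.17), Cxcr3 (-2.65 ± 0.24) and the granulocyte gene Mpo (-6.81 ± 0.83), genes whose naive level was higher in K215M than in WT. It was more positive for Isg15 (2.56 ± 0.18), the hexokinase Hk1 (0.72 ± 0.10), Tnfrsf4 (0.94 ± 0.19) and the collagen gene Col23a1 (3.82 ± 0.32), which was lower in the WT activated libraries than in every library of the other groups. Ifng also had a more negative change (-2.15 ± 0.51, adjusted p = 0.0142), a call lost with the compared groups alone (0.0581). The largest adjusted p among the other genes was 0.00305 (Tnfrsf4). The calls of Hk1, Tnfrsf4, Tbx21 and Ifng were lost with libraries 1 and 2 alone (adjusted p = 0.083, 0.198, 0.0581 and 0.309). Interferon-stimulated genes counted 29 higher, 0 lower and 9 not called (29 and 1 adjusted over the list alone, camera adjusted p = 1.13e-49). Memory-like genes counted 1 higher, 15 lower and 14 not called (1 and 16 adjusted over the list alone, camera adjusted p = 2.35e-10). Mitosis genes counted 0 higher, 15 lower and 18 not called (0 and 22 adjusted over the list alone). For mitosis genes camera gave an adjusted p of 2.35e-10, and 0.29 with an estimated correlation. Granulocyte markers counted 0 higher, 8 lower and 7 not called (0 and 11 adjusted over the list alone, camera adjusted p = 1.05e-12). Of 13 plasma cell markers, 0 were higher, 9 lower and 4 not called (0 and 9 adjusted over the list alone) (camera adjusted p = 1.51e-07, and 0.054 with an estimated correlation). Of 20 B cell markers, 0 were higher, 5 lower and 15 not called (0 and 6 adjusted over the list alone) (camera adjusted p = 2.7e-08, and 0.302 with an estimated correlation). Of 13 CD4 and regulatory T cell markers, 2 were higher, 5 lower and 6 not called (2 and 7 adjusted over the list alone) (camera adjusted p = 0.00172, and 0.054 with an estimated correlation). Of 13 heat shock genes, 5 were higher, 0 lower and 8 not called (9 and 0 adjusted over the list alone) (camera adjusted p = 1.08e-05, and 0.302 with an estimated correlation). The share of calls that were more positive was 40.5%, against 18.1% with total counts and 24.9% without the low-count filter, and 101 genes were called with libraries 1 and 2 of each group alone.

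Calls shared by the mutants against the same WT libraries were counted last. In activated cells, 319 genes were higher and 123 lower in both mutants (442 in the same direction), and 2686 went in opposite directions, where independent lists of these sizes would give 1226 and 1215. Unchanged groups simulated against the same WT libraries gave 0 shared calls. The correlation of log2 fold changes across genes, which are not independent replicates, was -0.0308 (0.482 in the simulation), and the covariance was -0.0303 against 0.0651. In naive cells, 323 genes were higher and 280 lower in both (603), and 51 went in opposite directions, where independent lists would give 140.8 and 137.5 and the simulation 0.05 shared calls. The naive correlation was 0.385 (0.496 in the simulation) and the covariance 0.218 against 0.0542, a difference of 0.164. The 3 WT libraries of a state cannot be split into separate controls, so part of the excess may come from the shared controls. Shared naive calls numbered 358, 378 and 346 without WT naive library 1, 2 or 3, and 388 without E134G naive library 2. With libraries 1 and 2 alone the shared calls were 108 in activated and 65 in naive cells. Pdcd1 (2.68 ± 0.29 and 2.96 ± 0.28), Tbx21 (1.37 ± 0.14 and 1.49 ± 0.14) and Ccl5 (2.28 ± 0.24 and 4.51 ± 0.25) were among the genes higher in naive E134G and naive K215M cells.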

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

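The tests of what the E134G activated libraries may be, with values 2697, 1.1 and 1.26, were chosen after the results were seen, and the splits of the libraries were planned before. The interaction test gave these differences in the response to activation. In E134G, 8401 genes differed. The differences in log2 fold change were -8.70 for Ifng, -8.20 for Gzmb, -5.54 for Tbx21, -5.05 for Pdcd1, -2.23 for Myc, -3.32 for Mcm5, -2.36 for Nop58, 1.03 for Tcf7, 1.14 for Sell and 1.10 for Card11. In K215M, 1542 genes differed. The differences were -2.15 for Ifng, -2.09 for Il2ra, -2.43 for Pdcd1, -1.16 for Tbx21, -2.65 for Cxcr3, -6.81 for Mpo, 2.56 for Isg15, 0.72 for Hk1, 0.94 for Tnfrsf4 and 3.82 for Col23a1.

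For the E134G interaction, 1 of 100 splits of the libraries, the real one, gave as many genes as 8401. The highest other split gave 8015. The other splits regroup libraries within a state and can keep part of the genotype difference, so this rank does not exclude chance. For the K215M interaction, 3 of 100 splits, the real one included, gave as many as 1542. Their share is under 0.05, but the highest other split gave 1791, more than the real one, so no conclusion on chance is drawn for either interaction. For each of the 9 comparisons of 3 against 3 libraries only 10 splits exist, which is too few for a share under 0.05. In each, only 1 of the 10 splits, the real one, gave as many genes, and the highest other split gave 0. The real numbers were 10232, 7416 and 10901 for activation in WT, E134G and K215M, 9968 and 3707 for the activated mutants, 1252 and 3365 for the naive mutants, and 10831 and 2998 between the mutants.

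The E134G activated libraries showed little of the induced program although 7416 genes changed: of 550 genes at least 4-fold higher in both WT and K215M, 146 rose and 133 fell, a ratio of 1.1, and 612 of the 889 lower genes fell. Naive libraries under an activated label are argued against by 2697 genes at least 2-fold apart between E134G activated and naive libraries. Full replacement of T cells is argued against by a sum of T cell markers of 2649 ± 179 CPM. That is 1.26 times the 2108 ± 38.9 CPM of WT activated libraries. A partial mixture with other cells stays open, since this sum was higher in WT naive (3646 ± 117 CPM) than in WT activated libraries. Culture without effective stimulation stays open, and so does an effect of the E134G change on the response to stimulation; they cannot be told apart, because no group was cultured without stimulation and the ratio of 1.1 describes the pattern itself, whatever its cause. Every statement on activated E134G cells, including the 8401 genes of the interaction, holds for these libraries whichever of these applies.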

How the results depend on the processing

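The alternative with libraries 1 and 2 of each group alone was chosen after seeing the data, and the others before. Among the 213 gene results named in the report, 2879 of 2958 comparisons with an alternative kept direction and side of the threshold, 60 lost the call, 7 gained one and 12 changed sign. Of these results 21 lost their call under some alternative. More genes had been considered for naming than were kept, and the named ones were chosen with their alternatives in view, so this share is no estimate for other genes. All sign changes were of uncalled values near 0. With total counts they were Nfkbia in activated E134G cells (0.0083) and, in activated K215M cells, Il2ra (-0.017) and Tnf (-0.015). In activated K215M cells the other changes were Il2ra and Tnf without the filter (-0.051 and -0.049) and with the compared groups alone (-0.027 and -0.025), Il2ra without K215M activated library 1 (-0.068), Gzmb without WT activated library 1 (0.21) or K215M activated library 2 (0.025), and Tnf without WT activated library 2 (-0.015) or K215M activated library 1 (-0.0025). Leaving out 1 library at a time, these ranged from -0.068 to 0.17 for Il2ra, from -0.33 to 0.21 for Gzmb and from -0.015 to 0.14 for Tnf. The cause was not tested.

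Libraries 1 and 2 alone have fewer samples and leave out a possible pool. Calls then numbered 4122 for E134G activation, 500 for activated K215M, 115 for naive E134G, 1232 for naive K215M and 822 between the naive mutants. They numbered 5480 and 101 for the E134G and K215M interactions, and 108 and 65 for calls shared in activated and naive cells. The comparison of the naive mutants gave 1632 with the compared groups alone, where fewer libraries set the spread. Lists past the threshold with an estimated correlation numbered 1 for WT activation, 5 and 0 for activated E134G and K215M, 3 and 9 for naive E134G and K215M, 0 and 9 between the activated and naive mutants, and 0 and 4 for the E134G and K215M interactions, against 19, 19, 15, 11, 19, 18, 16, 18 and 17. With fry the activated mutants differed in 28 lists. The cause was not tested.

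Leaving out 1 library at a time gave 9555 to 10135 genes for WT activation, 6489 to 7137 for E134G and 10527 to 10895 for K215M activation, 9039 to 9831 for activated E134G, 1905 to 4289 for activated K215M, 706 to 1414 for naive E134G, 2571 to 3391 for naive K215M, 10309 to 10648 and 2261 to 3380 between the activated and naive mutants, 7710 to 8453 and 1041 to 1862 for the E134G and K215M interactions, and 322 to 451 and 346 to 623 for shared calls in activated and naive cells. With the replicate number as a block, calls numbered 3411 for activated K215M and 1160 for naive E134G cells, and 1167 for the K215M interaction with genotype and number as the block. Scaling by total counts shifted the median log2 fold change by -0.158 for K215M activation, -0.145 between the activated mutants and -0.148 for the K215M interaction, and omitting the filter by 0.101 for WT activation. Depth limits genes with few counts: at 9663773 to 18880278 counts per library, 15136 of 30662 names with a count could be tested.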

Other observations

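The tests of library order and of the genes on or off in WT activated libraries (values 7.99, 0.00412, 0.151 and 6.32) were chosen after the results were seen. Genes on in 1 group alone, chosen after their values were seen, numbered 54 in K215M naive libraries, of which 48 were immunoglobulin genes; Igkc stood at 1360 ± 339 CPM there and 81.3 ± 10 CPM in WT naive libraries. Ctrb1 and Cel encode digestive enzymes of the pancreas. They ranged from 7.48 to 40.8 and from 5.36 to 23.5 CPM over the WT naive libraries and stood at 0 ± 0 and 0.0186 ± 0.0322 CPM in WT activated libraries. Gm47283 was off in WT naive libraries alone, at 0.256 ± 0.237 CPM against 9.81 to 161 CPM over all other libraries (114 ± 40.6 in E134G naive). So was Prss34. A peculiarity of WT naive libraries would enter WT activation, both naive mutant comparisons and both interactions. Gm10800 ranged from 6.63 to 99.2 CPM over the E134G naive libraries.

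Library 3 lay between libraries 1 and 2 in every group, for 67.9% to 90.1% of differing genes. A chance order is argued against, with the limit that the order had been seen: 1 number, whichever it is, would be the middle one in all 6 groups with a probability of 0.00412. Library 3 may be a pool of libraries 1 and 2 or of their RNA: against their best mixture it had a residual chi-square per gene of 1.57 to 7.99, above simulated pools without added noise (0.658 to 0.712) and below simulated independent libraries (14 to 19.3). The latter were simulated at a wider spread than WT naive or E134G activated libraries have (8.06 and 8.52 between libraries 1 and 2), so a pool cannot be told apart here from libraries that lie close together for another reason. No library is a copy of another, since the chi-square per gene between libraries of a group was 2.86 to 50.3.

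In the WT activated libraries alone, 14 genes were on and 3 off (Arsb, Col23a1 and 5830444B04Rik), named after their values were seen. A different genetic background of the mice behind these libraries may account for them; 2 pairs of the 16 genes with a position lay within 5 Mb, against a mean of 0.736 in 10000 random sets of genes (permutation test, p = 0.151), which decides nothing. A response to stimulation that both mutants lack may account for them too: 6.32% of the 933 genes at least 8-fold changed in WT (59) had no 2-fold change the same way in K215M. Both cannot be told apart with these values: WT naive libraries lack the pattern, but the labels do not say whether they came from the same mice as the WT activated ones.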
